A study of Mus musculus with 12 samples.

How the data were processed

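RNA levels were measured in back skin of mouse embryos at embryonic day 18.5 on 12 Illumina mouse bead arrays. The labels give 4 groups of 3 arrays: embryos lacking the type I keratin gene cluster with their own wild type, and embryos lacking the type II keratin gene cluster with their own wild type, all on a C57BL/6 background. Per the labels' protocols, total RNA was extracted with Trizol, cleaned on RNeasy columns with DNase I, checked on a Bioanalyser and turned into biotin-labelled cRNA with the Ambion MessageAmp kit. The labels do not say whether the arrays of a group come from separate embryos. By sex-linked transcripts every group except the type I knockout held both sexes, and so more than 1 embryo. Whether each array is a separate embryo stays unknown, so the p-values measure the spread between these samples, which may be partly technical.

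The deposited table holds, per the file headers, the average bead signal of each probe as an intensity that is not normalized and not background-subtracted, together with a detection p-value of each probe on each array, deposited by the authors. The scanner software and the way the detection p-value was computed are not given in the sources used here. The authors' processed table, also deposited, holds intensities of the same arrays. Its values showed that it is on a linear scale, background-subtracted and quantile normalized: medians were 16.3 to 16.4 on every array, 25.2% to 25.3% of values were negative, and each column had the rank order of its own array's signal (Spearman rho of 1). It was used only as an alternative, as log2 of the value floored at 0 plus 16. The plan had assumed that this table was on a log2 scale already.

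Signals were background-corrected by normexp, with the negative controls inferred from the detection p-values (798 steps of the detection p) and an offset of 16, then quantile normalized and put on a log2 scale with limma 3.58.1 in R 4.3.3. Of 25697 probes, 23978 had 1 gene symbol in the platform's annotation table, 0 had several and 1719 had none there. Entrez identifiers were looked up in a RefSeq table of assembly GRCm38.p6, which changed 0 symbols and lacked the identifiers of 16 probes. That assembly served for names and for the order of neighbouring genes, and no coordinates are given. A probe entered if its detection p was under 0.05 on at least 3 arrays, which kept 14744 probes. Each gene was represented by its entered probe with the highest mean, and a probe without a gene name stood for itself, giving 11163 features (10280 named genes and 883 unnamed probes), called genes from here on. Of 2607 genes with several entered probes, 3 in the type I comparison and 27 in the type II comparison had probes called in opposite directions, and 658 and 786 were called on some of their probes only. Probe sequences were not used here, so cross-hybridisation between close relatives such as the Lce1 or Sprr2 genes was not checked.

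Between 13272 and 13693 probes were detected per array (51.6% to 53.3%), with raw median signals of 107 to 150. With 3 arrays per group, the number of arrays limits the precision. The median standard error of a log2 fold change was 0.17. All 12 arrays entered 1 linear model with a term per group and 8 residual degrees of freedom, tested with limma's lmFit and eBayes and adjusted by Benjamini-Hochberg over all genes. Genes with an adjusted p under 0.05 are said to have risen, fallen or been called. The contrasts were each knockout minus its own wild type, the difference of these 2 changes, and the wild type of the type II series minus that of the type I series. Log2 fold changes are given ± their standard error, with 3 arrays per group throughout, and every adjusted p for a gene comes from this limma model. Of the genes named for the type I comparison 84 of 86, and for the type II comparison 96 of 100, had all knockout arrays beyond all wild-type arrays. The naming rule below favours such genes, since it requires this of the largest changes and takes the smallest p of each list. Over all genes the shares were 46.9% and 49.3%. Where a gene was not detected on any array of a group (detection p of 0.05 or more), the change is given as "at least N-fold", the mean of the brighter group over the mean, per array of the dimmer group, of the higher of the gene's own value and the lowest value of a detected probe. A gene detected on 1 or 2 arrays of a group keeps its fitted change. This holds for 25 called changes, which with signals below the lowest detected value raised to it moved by at most 0.37 and kept their sign.

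The design, the alternatives, the gene lists and the rule for naming genes were fixed before the data were examined. The rule takes for each knockout the keratins of the deleted cluster, the 8 genes with the largest rise and the 8 with the largest fall outside the deleted cluster among called genes whose knockout arrays all lie beyond all arrays of their wild type, up to 4 members of each list with the smallest p, and Tslp and Nfe2l2, which the series title names as TSLP and Nrf2. For the difference between the knockouts it takes the 4 largest in each direction, and for the wild-type groups the 3 largest in each direction. In total 37 lists were fixed. The type I and type II keratins are described gene by gene, and a sex-linked list served to read the sex of each array's sample, used only as a covariate. The other 34 lists (22 gene lists and 12 lists of cell type markers) were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation. List counts are also given adjusted over the list alone. List medians use fitted changes, and with genes below background in a group set at their bound 13 of the 68 medians moved as rounded here, by at most 0.53 (melanocytes, type I knockout). Camera sets a list against all other genes, whose median change was -0.11 in the type I and -0.08 in the type II comparison. No marker list other than those of skeletal muscle (1 gene) and of Schwann cells and nerve (1 gene) shared a measured member with another list.

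The alternatives were no background correction, median scaling in place of quantile normalization, the authors' processed values, no filter on dim probes, a filter at detection p under 0.01 on at least 6 arrays, the mean of all entered probes of a gene, a fit of each knockout with its own wild type only, eBayes with trend and robust settings, array weights, a block for the replicate number, a block for the number that opens each sample title, sex as a covariate, a threshold of at least 2-fold, Spearman's coefficient and leaving out each array in turn. The fit was tested on simulated data for the type I contrast over 11163 genes: of 50 genes changed by each size, 5 were recovered at a log2 change of 0.5, 37 at 1, 47 at 2 and 49 at 3, with 5 false calls among 10963 unchanged genes. In a simulation for the type I contrast, a list shifted by 0.5 was called and 0 of the 33 other lists were. Its noise was drawn independently for each gene, whereas the estimated correlation was, for example, 0.75 among the adipocyte markers. The simulation therefore does not show how often camera at the preset correlation calls lists of correlated genes.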

Results

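Back skin of embryos at day 18.5 was profiled on 12 bead arrays, 3 from embryos lacking the type I keratins, 3 from their wild type, 3 from embryos lacking the type II keratins and 3 from their wild type. Keratins of type I and type II pair to form the intermediate filaments of epithelial cells, so that the loss of either cluster removes the filaments' building partners. The series title places the study among questions of Nrf2, mitochondrial activity, barrier composition and the cytokine TSLP. Between 13272 and 13693 probes were detected per array. Arrays of 1 group correlated at 0.962 to 0.991 over all genes tested and arrays of different groups at 0.884 to 0.984. The first principal component, with 50.3% of the variance, parted all knockout arrays from all wild-type arrays, and the second, with 20.3%, parted the type I from the type II series in both genotypes, the knockouts further than the wild types.

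Most keratins of the deleted cluster lost their signal in each knockout. In the type I knockout, 9 of the 10 type I keratins detected on all wild-type arrays were not detected on any knockout array. Krt14, the type I keratin of basal keratinocytes, was at least 583-fold lower, Krt17 at least 276-fold, Krt15 at least 98.8-fold, Krt23 at least 58.3-fold, Krt27 at least 13.9-fold and Krt16 at least 13.8-fold. Krt10, the suprabasal type I keratin, was still detected on 1 knockout array and fell by 9.82 ± 0.46 on the log2 scale, or by 9.45 with signals below the lowest detected value raised to it. In the type II knockout, 6 of the 10 type II keratins detected on all wild-type arrays were not detected on any knockout array. Krt1 was at least 70.4-fold lower, Krt79 at least 68.8-fold, Krt73 at least 59.6-fold, Krt71 at least 56.0-fold and Krt5, the basal partner of Krt14, at least 50.4-fold. The other 4 stayed detectable in the knockout, which was not explained here: Krt8 on 3 of 3 arrays at a mean log2 signal of 7.42 (9.22 in wild type), Krt80 on 3 of 3 at 6.29 (5.89 in wild type), Krt7 on 2 and Krt78 on 1. Krt78 fell by 2.35 ± 0.32, Krt8 fell by 1.80 ± 0.47, Krt7 changed by -0.75 ± 0.27 and Krt80 by 0.39 ± 0.14. The calls of Krt7 (adjusted p = 0.0456, 0.00706 to 0.290 over the alternatives) and Krt80 (adjusted p = 0.0469, 0.0294 to 0.19) were lost under 15 and 19 of 24 alternatives. For Krt7 these include the fits without wild-type replicates 1 (0.151) or 2 (0.104) or knockout replicates 1 (0.0831), 2 (0.119) or 3 (0.0596) of its series, and without wild-type replicates 1, 2 or 3 or knockout replicate 2 of the other series (0.0593, 0.0568, 0.0536 and 0.0578). For Krt80 they include those without wild-type replicates 1 (0.0932), 2 (0.161) or 3 (0.0614) or knockout replicates 2 (0.147) or 3 (0.0747) of its series, and without wild-type replicates 1, 2 or 3 or knockout replicates 1 or 3 of the other series (0.0576, 0.0567, 0.0506, 0.0603 and 0.0501).

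The intact cluster also changed. In the type I knockout the stress keratins Krt6b and Krt6a rose, Krt6b by 9.29 ± 0.17 (detected on 1 of 3 wild-type arrays, 8.96 with signals raised likewise) and Krt6a at least 72.0-fold, and Krt7 rose by 1.68 ± 0.27, with 7 of 17 measured type II keratins and Krt18 rising and 0 falling (7 and 0 adjusted over the list alone). In the type II knockout Krt16, a stress keratin of type I, rose by 6.41 ± 0.39 and Krt17 by 0.82 ± 0.12. Krt15 fell by 2.24 ± 0.22, Krt35 fell by 2.61 ± 0.38 and Krt10 fell by 1.54 ± 0.46, with 2 of 14 measured type I keratins rising and 8 falling (2 and 8 adjusted over the list alone). The call of Krt10 (adjusted p = 0.0205, 1.98e-05 to 0.0781 over 24 alternatives) was lost with each knockout fitted with its own wild type only (0.0747), without wild-type replicate 1 (0.0529) or 2 (0.0588) and without knockout replicate 1 (0.0781) or 3 (0.0726). Krt14 changed by 0.20 ± 0.11 there, which was not called (adjusted p = 0.173).

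**Figure D1:**
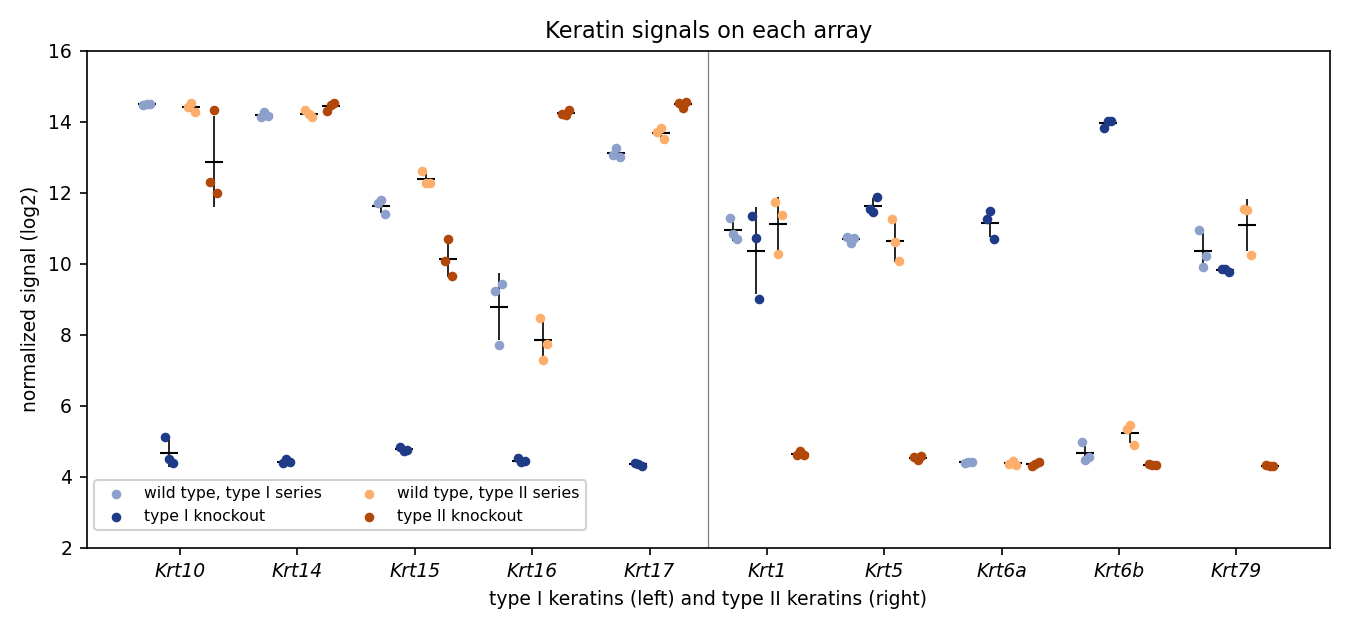
Normalized log2 signal of 5 type I and 5 type II keratins on each of the 12 arrays, with a point per array and a bar for the mean ± SD of the 3 arrays of a group. Krt6a and Krt6b are high only in the type I knockout among the groups plotted, and the mean of Krt16 is 14.2 in the type II knockout against 7.84 in its wild type.

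Among the largest rises in the skin without type I keratins, Sprr2g, a small proline-rich precursor of the cornified envelope, was at least 334-fold higher than in wild type, Klk6, a kallikrein-related serine protease, at least 230-fold, Sprr2e at least 131-fold, Sprr2f at least 83.6-fold and Sprr2k at least 71.0-fold. Csta3, a stefin, rose by 7.58 ± 0.32 on the log2 scale and the alarmin gene S100a8 by 6.82 ± 0.27. Tslp, the cytokine named in the series title, rose by 5.79 ± 0.28 (adjusted p = 6.19e-08). Outside the deleted cluster the deepest falls among called genes were smaller: Dapl1 fell by 3.79 ± 0.23, Lce1m, a late cornified envelope gene, fell by 2.79 ± 0.41, and Wfdc21 fell by 2.62 ± 0.35.

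Most measured genes of each barrier list rose in the type I knockout. Of 44 measured genes of the cornified envelope and epidermal differentiation complex, 28 rose and 2, Lce1m and Flg2, fell (30 and 2 adjusted over the list alone, camera adjusted p = 3.53e-17, adjusted p = 0.0565 with an estimated correlation). Sprr1a rose by 5.08 ± 0.24. The call of Flg2 (-1.83 ± 0.53, adjusted p = 0.0248, 0.00837 to 0.0899 over 24 alternatives) was lost without the filter on dim probes (0.0578), without wild-type replicates 1 (0.0899) or 2 (0.0504) and without knockout replicates 2 (0.0742) or 3 (0.088). Of 31 epidermal proteases and inhibitors, 27 rose and 0 fell (27 and 0 adjusted over the list alone, camera adjusted p = 3.53e-22, 0.00935 with an estimated correlation). Among them were Klk10 at 5.28 ± 0.31 and Klk13 at 4.63 ± 0.28. Of 38 enzymes of the barrier lipids, 20 rose and 2 fell (20 and 3 adjusted over the list alone, camera adjusted p = 2.41e-07, adjusted p = 0.266 with an estimated correlation). Degs2, which makes phytoceramides, rose by 4.27 ± 0.23, the lamellar granule transporter Abca12 by 2.11 ± 0.22 and the glucosylceramide synthase Ugcg by 1.69 ± 0.17. Cholesterol synthesis genes rose in 12 of 18 cases and fell in 0 (12 and 1 adjusted over the list alone, camera adjusted p = 7.3e-10, 0.044 with an estimated correlation). Members included Msmo1 at 2.34 ± 0.16 and Sqle at 2.03 ± 0.18. In the same samples the markers of dermal fibroblasts, adipocytes and skeletal muscle were lower, with list medians of -0.54, -1.38 and -0.83.

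Part of the inflammatory and stress genes rose as well. Of 32 alarmins, cytokines and chemokines, 9 rose and 2 fell (10 and 2 adjusted over the list alone, camera adjusted p = 0.00153, adjusted p = 0.216 with an estimated correlation). Il33, an alarmin of the interleukin 1 family, rose by 6.30 ± 0.19, Cxcl16 by 2.49 ± 0.25 and Il1rn by 1.59 ± 0.23. Of 25 antimicrobial and S100 genes, 14 rose and 2 fell (15 and 2 adjusted over the list alone, camera adjusted p = 2.92e-07, 0.00935 with an estimated correlation). Examples were S100a9 at 6.59 ± 0.21 and the beta-defensin Defb14 at 5.24 ± 0.46. Of 4 neutrophil markers in the same samples, 1 rose and 0 fell (list median 0.74, 0.50 with bounds). Of 32 stress keratinocyte, serpin and stefin genes, 14 rose and 0 fell (15 and 0 adjusted over the list alone, camera adjusted p = 1.53e-07, adjusted p = 0.216 with an estimated correlation). Among them were Serpinb6c at 3.83 ± 0.36, the growth factor gene Hbegf at 2.78 ± 0.27, the connexin gene Gjb2 at 2.63 ± 0.22 and Junb at 2.42 ± 0.25. Of 29 genes of endoplasmic reticulum stress and heat shock, 6 rose and 0 fell (6 and 0 adjusted over the list alone, camera adjusted p = 0.0118, adjusted p = 0.421 with an estimated correlation). Members included Hspa1a at 1.62 ± 0.29 and Hspb1 at 1.11 ± 0.19. No member of the 25 interferon response genes was called (0 adjusted over the list alone, 0 risen and 0 fallen, list median 0.15, camera adjusted p = 0.309), and the list was called without wild-type replicate 1 (0.0459, with 0.0459 to 0.838 over 25 alternatives).

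Nfe2l2, the gene of Nrf2, rose by 0.72 ± 0.23 in the type I knockout (adjusted p = 0.0355, 0.0039 to 0.121 over 24 alternatives). Its call was lost under 9 of them: without background correction (0.0648), with median scaling (0.057), without the filter on dim probes (0.0627) and without any 1 of the 6 arrays of the type I series. Leaving these out gave 0.0746, 0.0511 and 0.103 for wild-type replicates 1, 2 and 3 and 0.121, 0.0528 and 0.0729 for knockout replicates 1, 2 and 3. Of 41 Nrf2 target and glutathione genes, 16 rose and 1 fell (16 and 3 adjusted over the list alone, camera adjusted p = 6.13e-05, adjusted p = 0.216 with an estimated correlation). Examples were Gsta4 at 4.05 ± 0.32, the glutathione peroxidase Gpx2 at 3.64 ± 0.27, the cystine transporter Slc7a11 at 2.95 ± 0.21 and Akr1b8 at 2.25 ± 0.17. Of 70 respiratory chain and ATP synthase genes, 1 rose and 13 fell (0 and 9 adjusted over the list alone, camera adjusted p = 0.000516, adjusted p = 0.549 with an estimated correlation). Sdhb fell by 0.98 ± 0.19 and Cox4i1 fell by 0.61 ± 0.12, and the list's median was -0.27. Skeletal muscle and adipocyte markers fell further in the same samples (list medians -0.83 and -1.38), and muscle is rich in respiratory chain transcripts. In the type II knockout these markers had still lower medians (-1.33 and -1.58). The respiratory chain list was not called there, however (median -0.12, camera adjusted p = 0.488). Whether less muscle or fat lowered the respiratory chain genes was not tested. Of 25 genes of glucose transport, glycolysis and hypoxia, 9 rose and 3 fell (10 and 3 adjusted over the list alone, camera adjusted p = 0.000516, adjusted p = 0.421 with an estimated correlation). Among them were Egln3 at 2.33 ± 0.22, Ndrg1 at 2.03 ± 0.18 and the glucose transporter Slc2a1 at 1.83 ± 0.16.

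Most desmosome genes rose in type I knockout skin, and some genes of the hemidesmosome and basement membrane list fell. Of 11 desmosome genes, 9 rose and 0 fell (9 and 0 adjusted over the list alone, camera adjusted p = 2.08e-07, 0.00998 with an estimated correlation). Members included the cadherin Dsg1b at 3.37 ± 0.32, Dsg3 at least 5.34-fold higher and Perp at 1.95 ± 0.19. Of 21 genes of tight, gap and adherens junctions, 9 rose and 0 fell (9 and 0 adjusted over the list alone, camera adjusted p = 1.07e-05, adjusted p = 0.0679 with an estimated correlation). Examples were the barrier transcription factors Grhl3 at 2.53 ± 0.22 and Grhl1 at 1.68 ± 0.18 and the claudin Cldn1 at 1.98 ± 0.23. Of 19 hemidesmosome and basement membrane genes, 0 rose and 5 fell (0 and 5 adjusted over the list alone, camera adjusted p = 0.0333, adjusted p = 0.41 with an estimated correlation). Among them were Col7a1, the anchoring fibril collagen, at -0.88 ± 0.17 and Dst at -0.83 ± 0.15. Dermal fibroblast markers fell in the same samples, 12 of 16 with a list median of -0.54. The call of this list was also lost with median scaling (adjusted p = 0.0606), with the stricter filter (0.0507), with the replicate block (0.0532), without wild-type replicates 1 (0.0848) or 3 (0.0516) and without knockout replicate 2 (0.0544), in a range of 0.00254 to 0.41 over 25 alternatives. Of 22 basal keratinocyte genes, 9 rose and 3 fell (11 and 4 adjusted over the list alone, camera adjusted p = 0.00131, adjusted p = 0.266 with an estimated correlation). Members included Sfn at 2.94 ± 0.19 and the differentiation factor Zfp750 at 1.80 ± 0.17.

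Most fibroblast and adipocyte markers fell in the type I knockout, as did some hair follicle, cell cycle, muscle and endothelial genes. Of 26 hair follicle and placode genes, 2 rose and 10 fell (2 and 10 adjusted over the list alone). Examples were Edar at -1.23 ± 0.22 and Lhx2 at -1.03 ± 0.14. As a list they were not called (camera adjusted p = 0.051), in a range of 0.0234 to 0.488 over 25 alternatives. They were called with the authors' values (0.0492), without the filter on dim probes (0.0369), with the stricter filter (0.0401) and with each knockout fitted with its own wild type only (0.042), and also without wild-type replicate 2 (0.0234) or 3 (0.0362) or knockout replicate 2 (0.0416) of the type I series, and without wild-type replicate 2 (0.0353) or 3 (0.0349) of the type II series. Of 31 cell cycle genes, 0 rose and 7 fell (0 and 7 adjusted over the list alone, camera adjusted p = 0.0112, adjusted p = 0.587 with an estimated correlation). Ccnd1, the cyclin D1 gene, was at -1.16 ± 0.23. Without wild-type replicate 2 the cell cycle list was not called (adjusted p = 0.0668, 0.000296 to 0.587 over 25 alternatives). Of 16 dermal fibroblast markers, 1 rose and 12 fell (1 and 12 adjusted over the list alone, camera adjusted p = 0.000599, adjusted p = 0.301 with an estimated correlation). Members included the elastin crosslinker Loxl1 at -0.97 ± 0.13 and Sparc at -0.55 ± 0.11. Of 8 adipocyte markers, 0 rose and 7 fell (0 and 7 adjusted over the list alone, camera adjusted p = 0.00652, adjusted p = 0.484 with an estimated correlation). The leptin gene Lep was at -1.49 ± 0.30. Of 22 skeletal muscle markers, 0 rose and 7 fell (0 and 10 adjusted over the list alone, camera adjusted p = 0.00126, adjusted p = 0.488 with an estimated correlation). Actn3, a muscle actinin, was at -1.25 ± 0.29. Of 10 endothelial markers, 0 rose and 2 fell (0 and 2 adjusted over the list alone, list median -0.34, camera adjusted p = 0.0364, adjusted p = 0.453 with an estimated correlation). The endothelial call was also lost with a covariate for sex (0.0658), without wild-type replicates 2 (0.0585) or 3 (0.0516) and without knockout replicates 2 (0.0544) or 3 (0.0671), in a range of 0.00986 to 0.453 over 25 alternatives.

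Over all genes, 3105 of 11163 (27.8%) were called in the type I knockout, 1359 higher and 1746 lower, of which 645 and 185 changed at least 2-fold and 69 and 8 at least 8-fold. The counts were 1095 higher and 1013 lower without knockout replicate 1, 1115 and 1073 without knockout replicate 2, and 1828 and 2829 with array weights, so that which direction had more calls depended on the arrays. The groups did not overlap for 5237 genes (46.9%), where chance gives 10%. The remaining genes among the 8 deepest falls outside the deleted cluster were Cfap57 (-2.39 ± 0.20), Adh1 (-2.20 ± 0.28), Cidec (-2.19 ± 0.66), Nmu (-2.18 ± 0.49) and Mrap (-2.13 ± 0.70). The calls of Cidec (adjusted p = 0.0292, 0.000595 to 0.107 over the alternatives) and Mrap (adjusted p = 0.0408, 0.00179 to 0.154) were lost under 5 and 9 of 24 alternatives. The arrays whose omission ended the call were wild-type replicates 1 and 2 (0.0503 and 0.107) and knockout replicates 1 and 2 (0.0897 and 0.0898) for Cidec. For Mrap they were wild-type replicates 2 and 3 (0.154 and 0.0532), knockout replicates 1 and 2 (0.121 and 0.127) and wild-type replicates 1 and 2 of the other series (0.0527 and 0.0518).

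In the skin without type II keratins, Lce1m fell by 6.26 ± 0.41, the filaggrin relative Flg2 fell by 5.40 ± 0.53, the hornerin gene Hrnr fell by 5.22 ± 0.67 and Lor, which encodes loricrin, fell by 4.84 ± 0.65. Sprr2g was at least 167-fold higher, Sprr2e at least 84.6-fold and Sprr2f at least 66.0-fold, Sprr2d rose by 7.09 ± 0.62, Csta3 by 6.83 ± 0.32, Sprr1b by 6.81 ± 0.51 and S100a9 by 6.44 ± 0.21. Tslp rose by 6.27 ± 0.28 (adjusted p = 5.92e-08) and Nfe2l2 by 1.69 ± 0.23 (adjusted p = 0.000205).

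Barrier genes moved both ways in the type II knockout. Of 44 cornified envelope and differentiation complex genes, 19 rose and 13 fell (21 and 13 adjusted over the list alone, list median 0.47, camera adjusted p = 0.0242, adjusted p = 0.509 with an estimated correlation). The list was also not called with the replicate block (0.0605), without wild-type replicate 2 (0.0866) and without knockout replicate 2 (0.0591), in a range of 0.00146 to 0.509 over 25 alternatives. The 13 that fell were Lor, Flg2, Hrnr, Casp14, which was picked out after its values were seen, and 9 genes of the Lce1 family. Other deep falls were Serpina12 (-5.51 ± 0.67), the histidine ammonia-lyase gene Hal (-5.20 ± 0.52), Cyp2b19 (-4.87 ± 0.37) and Gm94 (-4.34 ± 0.61). Of 31 epidermal proteases and inhibitors, 15 rose and 3 fell (16 and 3 adjusted over the list alone, camera adjusted p = 7.33e-06, adjusted p = 0.206 with an estimated correlation). Members included Slpi, an inhibitor of neutrophil elastase, at least 31.8-fold higher, the transcription factor Elf3 at 4.33 ± 0.37 and Klk6 at 4.29 ± 0.34. Of 38 barrier lipid enzymes, 8 rose and 6 fell (8 and 6 adjusted over the list alone). Examples were Degs2 at 3.25 ± 0.23, Abca12 at 1.48 ± 0.22 and the desaturase Fads1 at -1.02 ± 0.15. That list was not called (camera adjusted p = 0.982, placed upward by camera although its median was -0.22 and its mean -0.12). Of 18 cholesterol synthesis genes, 10 rose and 0 fell (10 and 0 adjusted over the list alone, camera adjusted p = 0.000758, adjusted p = 0.277 with an estimated correlation). Among them were Lss at 1.62 ± 0.18 and Msmo1 at 1.06 ± 0.16. In the same samples the markers of fibroblasts, adipocytes and skeletal muscle were lower, with list medians of -0.58, -1.58 and -1.33.

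Many inflammatory, hypoxia and stress genes rose in the type II knockout. Of 32 alarmins, cytokines and chemokines, 16 rose and 3 fell (16 and 3 adjusted over the list alone, camera adjusted p = 0.000787, adjusted p = 0.218 with an estimated correlation). Members included Il33 at 5.55 ± 0.19, the neutrophil attractant Cxcl1 at 4.78 ± 0.50 and Cxcl16 at 3.12 ± 0.25. Of 25 antimicrobial and S100 genes, 15 rose and 2 fell (15 and 2 adjusted over the list alone, camera adjusted p = 2.77e-05, 0.0167 with an estimated correlation). Examples were S100a8 at 5.89 ± 0.27 and Defb14 at 5.51 ± 0.46. Of 4 neutrophil markers in the same samples, 3 rose and 0 fell (list median 1.00, 0.70 with bounds). Of 25 genes of glucose transport, glycolysis and hypoxia, 19 rose and 1 fell (20 and 2 adjusted over the list alone, list median 1.33, camera adjusted p = 1.22e-10, adjusted p = 0.206 with an estimated correlation). The hypoxia-induced genes Adm and Ndrg1 rose by 5.46 ± 0.32 and 4.04 ± 0.18, Slc2a1 by 3.14 ± 0.16 and the phosphofructokinase Pfkp by 2.76 ± 0.18. Of 32 stress keratinocyte, serpin and stefin genes, 19 rose and 3 fell (20 and 3 adjusted over the list alone, camera adjusted p = 1.65e-08, adjusted p = 0.218 with an estimated correlation). Among them were Epgn at 4.97 ± 0.48, Hbegf at 3.08 ± 0.27 and Junb at 3.03 ± 0.25. Of 29 genes of endoplasmic reticulum stress and heat shock, 9 rose and 3 fell (10 and 3 adjusted over the list alone, camera adjusted p = 0.0242, adjusted p = 0.454 with an estimated correlation). Members included Hspa1a at 2.41 ± 0.29 and Trib3 at least 2.31-fold higher. That list was also not called with the stricter filter (0.0689), without wild-type replicate 1 (0.0554) and without knockout replicate 3 (0.258), in a range of 0.00124 to 0.454 over 25 alternatives. Of 25 interferon response genes, 9 rose and 1 fell (10 and 1 adjusted over the list alone, camera adjusted p = 0.00041, adjusted p = 0.454 with an estimated correlation). Examples were Mx2 at 1.36 ± 0.34 and Isg15 at 1.17 ± 0.29.

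Nrf2 targets went both ways in the type II knockout. Of 41 Nrf2 target and glutathione genes, 12 rose and 8 fell (12 and 8 adjusted over the list alone), and the list was not called (median 0.05, camera adjusted p = 0.199). Akr1b8 rose by 3.51 ± 0.17 and Gsta4 by 2.60 ± 0.32, whereas Gsta1 fell by 2.89 ± 0.33 and Gsta2 fell by 2.51 ± 0.31. Of 70 respiratory chain and ATP synthase genes, 3 rose and 7 fell (0 and 0 adjusted over the list alone), and that list was not called either (median -0.12, camera adjusted p = 0.488).

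Desmosome genes rose in the type II knockout too, 9 of 11 with 0 falling (9 and 0 adjusted over the list alone, camera adjusted p = 3.01e-07, 0.0167 with an estimated correlation). Dsg3 rose by 4.32 ± 0.26, Dsc3 by 2.77 ± 0.27 and the plakophilin Pkp1 by 1.36 ± 0.16. Of 21 genes of tight, gap and adherens junctions, 12 rose and 1 fell (14 and 3 adjusted over the list alone, camera adjusted p = 0.0002, adjusted p = 0.206 with an estimated correlation). Among them were Cldn4 at 3.97 ± 0.35 and Grhl3 at 2.26 ± 0.22. Of 19 hemidesmosome and basement membrane genes, 5 rose and 4 fell (5 and 4 adjusted over the list alone). Members included the integrin genes Itgb4 at 1.60 ± 0.17 and Itga6 at 0.99 ± 0.26, and Dst at -0.74 ± 0.15. This list was not called (camera adjusted p = 0.982), and its median of -0.16 and mean of 0.05 differed in sign. Of 22 basal keratinocyte genes, 10 rose and 4 fell (10 and 4 adjusted over the list alone, camera adjusted p = 0.0227, adjusted p = 0.446 with an estimated correlation). Sfn rose by 2.79 ± 0.19.

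Most measured hair follicle, cell cycle, skeletal muscle, fibroblast and adipocyte genes fell in the type II knockout. Of 26 hair follicle and placode genes, 1 rose and 15 fell (1 and 16 adjusted over the list alone, camera adjusted p = 0.0011, adjusted p = 0.346 with an estimated correlation). Among them were Dlx3 at -2.04 ± 0.24, Shh at -1.95 ± 0.20 and Lhx2 at -1.66 ± 0.14. Of 31 cell cycle genes, 0 rose and 21 fell (0 and 22 adjusted over the list alone, camera adjusted p = 7.65e-06, adjusted p = 0.411 with an estimated correlation). Members included Ccnd1 at -1.40 ± 0.23, Cdc45 at -0.89 ± 0.14 and Nusap1 at -0.85 ± 0.14. Of 22 skeletal muscle markers, 0 rose and 16 fell (0 and 19 adjusted over the list alone, camera adjusted p = 5.23e-06, adjusted p = 0.411 with an estimated correlation). The troponin gene Tnnt3 was at -1.72 ± 0.22. Of 16 fibroblast markers, 0 rose and 10 fell (0 and 10 adjusted over the list alone, camera adjusted p = 0.000577, adjusted p = 0.346 with an estimated correlation). Loxl1 was at -1.33 ± 0.13. Of 8 adipocyte markers, 0 rose and 6 fell (0 and 7 adjusted over the list alone, camera adjusted p = 0.00989, adjusted p = 0.454 with an estimated correlation). Lep was at least 7.51-fold lower. Of 8 mast cell markers, 0 rose and 4 fell (0 and 6 adjusted over the list alone, camera adjusted p = 0.0242, adjusted p = 0.454 with an estimated correlation). Examples were the mast cell proteases Mcpt4 at -2.48 ± 0.58, Cpa3 at -2.42 ± 0.58 and Cma1 at -2.41 ± 0.53. The mast cell list was also not called without knockout replicates 1 (0.0673) or 2 (0.0591), in a range of 0.000227 to 0.454 over 25 alternatives. Endothelial markers were not called as a list (1 rose, 1 fell, 1 and 1 adjusted over the list alone, median 0.06, mean -0.04, camera adjusted p = 0.799).

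Over all genes, 4183 of 11163 (37.5%) were called in the type II knockout, 1746 higher and 2437 lower, of which 732 and 620 changed at least 2-fold and 71 and 28 at least 8-fold. The groups did not overlap for 5499 genes (49.3%), where chance gives 10%. With median scaling in place of quantile normalization, 1237 were higher and 2828 lower, so that the share of higher calls was 30.4% in place of 41.7%.

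**Figure D2:**
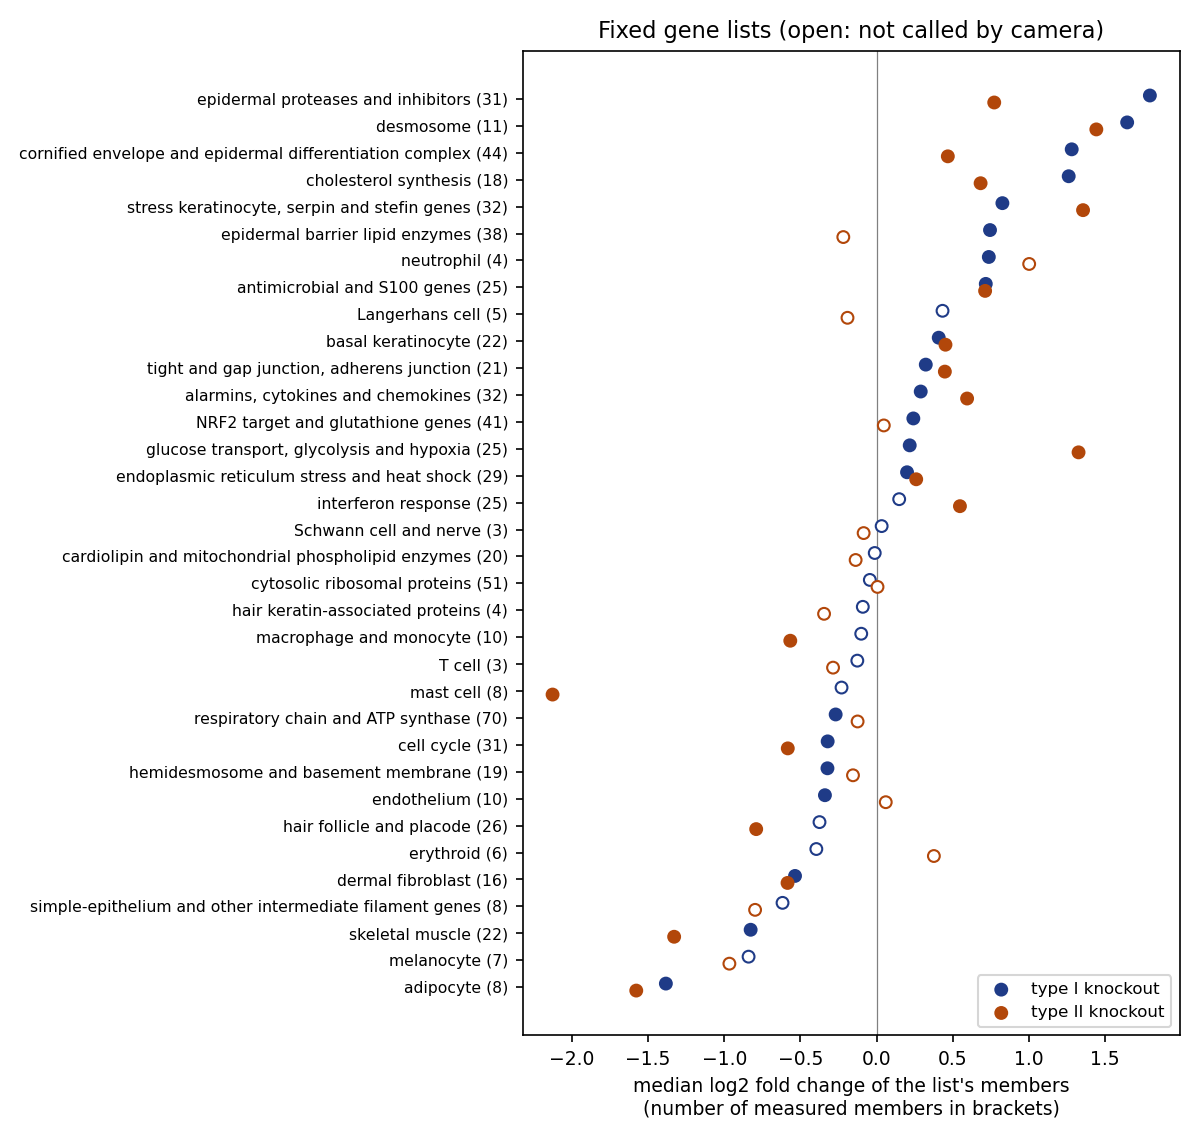
Median log2 fold change of the measured members of each of the 34 fixed lists in the type I knockout (blue) and the type II knockout (orange), each against its own wild type, with open circles for lists not called by camera at the preset correlation. Proteases have the highest median in the type I knockout (1.79), and mast cell markers the lowest in the type II knockout (-2.13).

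Comparing the knockouts asks which changes follow the loss of either keratin type. Of 11132 genes outside both keratin lists, 927 rose in both knockouts, where independent lists would share 212, and 1136 fell in both, where independent lists would share 377. The 2063 genes called in the same direction compare with 36 called in opposite directions. The log2 fold changes correlated across genes at Pearson's r = 0.719 and Spearman's rho = 0.682, a description only, since genes are not independent replicates. Each knockout has its own wild type, so no control array is shared. Tslp, Il33, S100a8, S100a9, Csta3, Sprr2e, Sprr2f, the desmosome gene Dsg1b and the transcription factor Grhl3 rose in both, and Dapl1, Wfdc21, Shh, Lhx2 and Loxl1 fell in both. The changes of Tslp differed by 0.47 ± 0.39 (adjusted p = 0.594) and those of Nfe2l2 by 0.97 ± 0.32 (adjusted p = 0.146), with 95% intervals of -0.38 to 1.33 and 0.27 to 1.67, and neither difference was called. That of Nfe2l2 (0.00721 to 0.305 over 23 alternatives) was called with array weights (1.16, adjusted p = 0.0232) and without type II knockout replicate 3 (1.28, adjusted p = 0.00721).

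Of all 11163 genes, keratins included, the change differed between the knockouts for 342, 136 with a more positive and 206 with a more negative change in the type II knockout, of which 97 and 189 differed at least 2-fold. Of the 342, 17 were keratins (6 positive and 11 negative), which leaves 325 other genes, 130 positive and 195 negative. The largest positive differences were those of Espn (3.53 ± 0.59), Cxcl1 (3.36 ± 0.70), Adm (3.22 ± 0.45) and the stress-response factor Atf3 (3.20 ± 0.45), and the largest negative ones those of Hrnr (-4.87 ± 0.94), Serpinb11 (-4.81 ± 0.50), Lor (-4.63 ± 0.92) and Gm94 (-4.60 ± 0.86). Serpinb11 rose by 5.47 ± 0.35 in the type I knockout and changed by 0.65 ± 0.35 in the type II knockout (adjusted p = 0.167, 0.0233 to 0.647 over 24 alternatives, called without knockout replicate 3 at 0.0233). Lor changed by -0.21 ± 0.65 and Hrnr by -0.35 ± 0.67 in the type I knockout (adjusted p = 0.84 and 0.732). The calls of the differences of Cxcl1 (adjusted p = 0.0252, 0.00275 to 0.0668 over 22 alternatives), Hrnr (0.0171, 0.000502 to 0.054 over 23) and Lor (0.0201, 1.56e-05 to 0.0594 over 23) were lost under 10, 4 and 5 of these. Leaving out type I knockout replicate 1 or wild-type replicate 1 of the type II series ended all 3 calls, with adjusted p of 0.0607 and 0.0618 for Cxcl1, 0.0504 and 0.054 for Hrnr and 0.0577 and 0.0559 for Lor, and so did wild-type replicate 3 of the type I series for Cxcl1 (0.0542) and Lor (0.0501). The call of Cxcl1 was also lost without wild-type replicates 1 (0.0545) or 2 (0.0611) or knockout replicate 2 (0.0551) of the type I series, and without wild-type replicates 2 (0.051) or 3 (0.0595) or knockout replicate 1 (0.0582) of the type II series. The count of 342 was 207 without wild-type replicate 2 and 226 without replicate 3 of the type I series, 188 and 194 without type I knockout replicates 1 and 2, 170 and 190 without wild-type replicates 1 and 3 of the type II series, and 673 without type II knockout replicate 3. It was 825 with array weights and 539 with the block for the title number, with 48.8% and 49.7% positive in place of 39.8%. With median scaling, 73 differences were positive and 215 negative, a share of 25.3% positive.

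**Figure D3:**
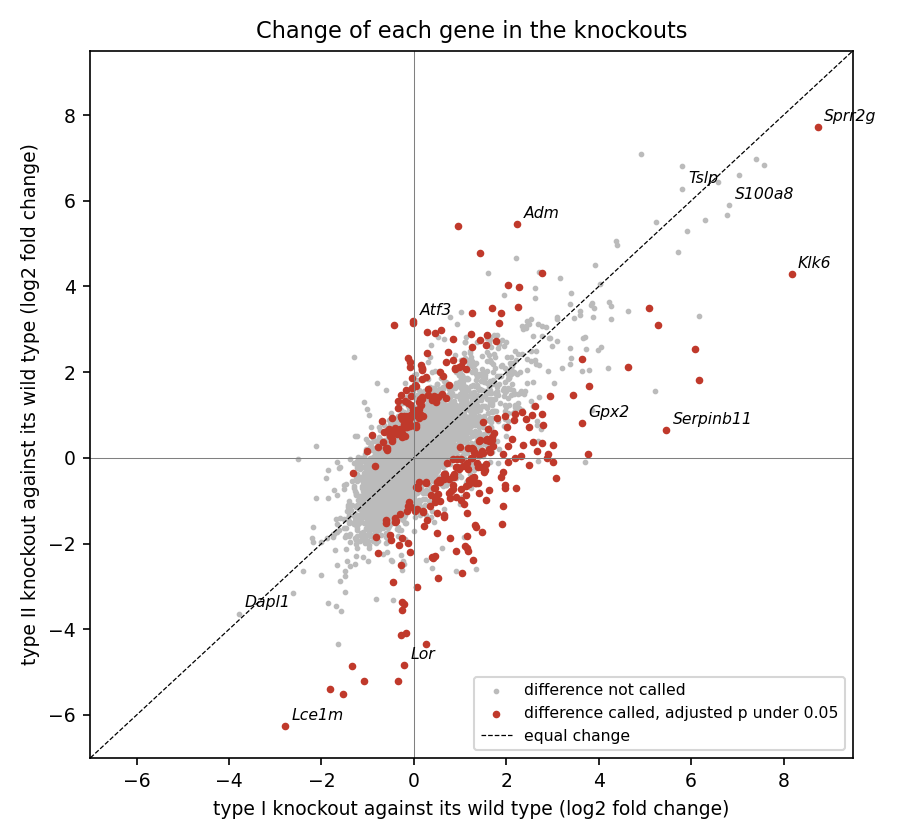
Log2 fold change of each of 11132 genes in the type I knockout (horizontal axis) and the type II knockout (vertical axis), each against its own wild type, with a point per gene, red where the difference of the changes was called, and a dashed line of equal change. Tslp, S100a8 and Dapl1 lie near the line, Klk6, Gpx2 and Serpinb11 below it, and Lor and Lce1m far below 0 on the vertical axis (genes below background in a group are drawn at their fitted change).

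The wild-type groups, which both carry a C57BL/6 label, differed in 171 genes, 67 higher and 104 lower in the type II series, with 1912 genes at an unadjusted p under 0.05. Cholesterol synthesis genes were higher in the wild type of the type II series, 7 of 18 called and 0 lower (13 and 1 adjusted over the list alone, list median 0.71, camera adjusted p = 3.38e-09, adjusted p = 0.186 with an estimated correlation). Among them were Lss (0.99 ± 0.18) and Msmo1 (0.98 ± 0.16). Hair follicle (list median 0.29, camera adjusted p = 0.00146) and cell cycle genes (0.26, 0.00146) were also called as higher there, and respiratory chain (-0.15, 0.000499) and hypoxia and glycolysis genes (-0.20, 0.00742) as lower, none with an estimated correlation (0.945 each), with 1 member called, a respiratory chain gene. By fitted change, Pou6f1 (at least 4.48-fold higher), Lars2 (2.65 ± 0.41) and Krt8 (2.29 ± 0.47) were the highest, and Paip1 (at least 10.9-fold lower), the tachykinin gene Tac1 (-3.42 ± 0.40) and the myosin light chain gene Myl3 (-2.66 ± 0.38) the lowest. The calls of Krt8 (adjusted p = 0.0381, 0.0132 to 0.0959) and Lars2 (0.012, 1.18e-05 to 0.0505) were lost under 11 and 1 of 21 alternatives, and those of Lss (0.0213, 0.00447 to 0.0855) and Msmo1 (0.0153, 0.00253 to 0.0658) under 3 and 4. Without wild-type replicates 1, 2 and 3 of the type I series Krt8 had 0.081, 0.089 and 0.0959, without its knockout replicates 0.0641, 0.0643 and 0.0539, and without wild-type replicates 1 and 2 of the type II series 0.0779 and 0.0804. Lars2 was lost without wild-type replicate 2 of the type II series (0.0505), Lss without wild-type replicate 3 of the type I series (0.0791) or replicates 1 or 3 of the type II series (0.0855 and 0.0689), and Msmo1 without wild-type replicates 2 or 3 of the type I series (0.0538 and 0.0505) or 1 or 2 of the type II series (0.0658 and 0.057). The count of 171 was 779 with array weights, 109 without the filter on dim probes, 60 and 48 without wild-type replicates 2 and 3 of the type I series, 82, 83 and 111 without type I knockout replicates 1, 2 and 3, and 41, 39 and 85 without wild-type replicates 1, 2 and 3 of the type II series.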

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

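The tests of the late cornified genes (against the barrier lipid enzymes, and with a knockout array left out) and that of the lists against the wild-type difference were chosen only after those results were seen.

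The results collected here are those whose change differed between the knockouts in the test of the difference itself. They comprise 342 genes, 136 with a more positive and 206 with a more negative change in the type II knockout. Of the 342, 17 were keratins. Of the 34 named genes among the other 325, the change was more positive in the type II knockout for Espn (3.53), Cxcl1 (3.36), Adm (3.22), Atf3 (3.20), Ndrg1 (2.01), Dsg3 (1.56), Mbp (1.32), Pfkp (1.32), Slc2a1 (1.31), Itgb4 (1.29), Akr1b8 (1.26) and Trib3 (1.16), each as the difference of the log2 fold changes. The change was more negative there for the small proline-rich genes Sprr2g (-1.02) and Sprr1a (-1.58), the proteases Klk10 (-2.18), Klk13 (-2.50) and Klk6 (-3.88), and the detoxification genes Slc7a11 (-1.52), Gsta2 (-2.22), Gsta1 (-2.44) and Gpx2 (-2.83). It was also more negative for Msmo1 (-1.28), Dlx3 (-1.72), Gm5477 (-3.11, a gene within the type II cluster), Cyp2b19 (-3.52), Serpina12 (-3.99), Hal (-4.12), Gm94 (-4.60) and Serpinb11 (-4.81). The same held for members of the cornified envelope list, Casp14 (-3.17), Lce1m (-3.47), Flg2 (-3.57), Lor (-4.63) and Hrnr (-4.87). The calls of 17 of these 34 differences were lost under at least 1 alternative, with those of Serpina12 (adjusted p = 0.0438, 0.00184 to 0.12), Dsg3 (0.0443, 0.00517 to 0.122), Casp14 (0.0338, 4.33e-05 to 0.0954), Sprr2g (0.0375, 0.00664 to 0.101) and Cxcl1 (0.0252, 0.00275 to 0.0668) lost under 16, 14, 12, 12 and 10 of them. For 11 of the 34 a group was detected on fewer than 3 arrays, so that the fitted difference depends on the background. With signals below the lowest detected value raised to it, the 6 of these with a group not detected on any array were at -3.55 (Klk6), 1.87 (Dsg3), -2.86 (Gm5477), 0.96 (Trib3), -1.003 (Sprr2g) and -2.82 (Gpx2), and none of the 11 changed sign or moved by more than 0.33. The difference of Mbp was lost with the mean of all its probes (adjusted p = 0.29, 0.000503 to 0.29 over 23 alternatives).

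By camera on the same difference, 16 lists were called at the preset correlation and 0 of these with an estimated correlation. A lower change in the type II knockout was found for the cornified envelope genes (median difference -1.31), proteases (-0.93), barrier lipid enzymes (-0.63), cholesterol synthesis (-0.52), hair follicle genes (-0.46), Nrf2 targets (-0.31), cell cycle genes (-0.32), and the markers of mast cells (-2.06), skeletal muscle (-0.56) and macrophages (-0.46). A higher change there was found for hypoxia and glycolysis genes (0.72), interferon response genes (0.34), hemidesmosome genes (0.29), respiratory chain genes (0.17), and the markers of erythroid cells (0.87) and endothelium (0.41). The lowest adjusted p with an estimated correlation was that of the proteases, at 0.113.

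The 342 genes whose change differed were set against 100 splits of the arrays, and 7 of these, the real one included, gave as many genes, so chance is not excluded by this count. The other 6 all kept the knockout arrays parted as labelled and rearranged the wild-type arrays (12 splits of that kind were drawn), while with the knockout arrays mixed the highest count was 3. The highest, 1773, several times the real count, came from exchanging the wild-type groups between the series, which points to a structure of the samples: arrays of a series shared differences in both genotypes, with a correlation across genes of 0.337 between the series difference in wild type and that in the knockouts, and 150 of the 171 genes differing between the wild-type groups had the same sign between the knockouts. Tested against the labels, a difference between the wild-type groups would account for genes that differ more there than between the knockouts, which were 8.62% of 325, and 91.8% of the 342 were still called with a covariate for sex, so neither accounts for most of the pattern among genes. Among the 16 lists, 4 scores differed more between the wild-type groups than between the knockout groups: cholesterol synthesis (0.57 ± 0.09 against 0.02 ± 0.09), hair follicle (0.35 ± 0.10 against -0.03 ± 0.10), cell cycle (0.33 ± 0.16 against -0.05 ± 0.16) and respiratory chain genes (-0.18 ± 0.09 against 0.00 ± 0.09). Msmo1 differed by 0.98 between the wild-type groups. For these 4 a difference between the wild-type groups stays open beside a different response. What stays open for the rest is a different response to the loss of each keratin type, which the design names and which was not tested further, and a series effect that is not the same in both genotypes.

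The 13 members of the cornified envelope list that fell in the type II knockout, picked out by that fall and called late cornified genes here, form the other pattern weighed. The whole list had 19 risen members and a median of 0.47. Their mean score changed by -3.75 ± 0.37, against -0.12 ± 0.16 for the barrier lipid enzymes, which are made in the upper layers too. A loss of the outermost layers from the samples would lower both. The 13 genes were picked by their fall, however, and the enzymes were not. Of the enzymes 8 rose and 6 fell in this knockout, and a rise such as that of Degs2 (3.25) could hide a loss. The comparison therefore cannot exclude a loss of these layers. A single aberrant knockout array was not the source, since with each knockout array of the series left out in turn 13 or 14 of the 44 genes of the list fell, the same 13 among them. Cross-hybridisation among the Lce1 probes was not tested and may make their 9 values depend on each other, though Lor, Flg2, Hrnr and Casp14 fell as well. Besides a loss of the outermost layers, a lower expression of these genes after the loss of the type II keratins, which the design names, stays open. This lower expression was not tested here. Measuring their transcripts by another method in isolated upper epidermis would test it.

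For the counts of called genes within a series, the 10 splits of 6 arrays are too few for a share under 0.05: the real split was the only 1 of 10 as large in the type I series (3105 genes, highest other 2), in the type II series (4183, highest other 1), and among the wild-type arrays (171, highest other 3). For the lists called the splits are likewise too few, with 1 of 10 splits as large in each series (21, highest other 18, and 19, highest other 18). Unlike the gene counts, these list counts were nearly reached by a split that mixed the genotypes. At the preset correlation the number of called lists therefore sets the real grouping apart only a little. For the correlation of the changes (0.719, highest other 0.633), 1 of 100 splits, the real one, was as large. The other splits mix knockout and wild type within a series or exchange them, which weakens or reverses the genotype effect. They therefore cannot tell whether the 2 responses are more alike than chance would give. For the genes called in the same direction in both knockouts (2063, highest other 36) the real split was also the only 1 of 100 as large. That comparison could not have come out otherwise. In the 98 splits that mixed the genotypes in a series, at most 2 genes were called in the series with fewer calls, and the 36 came from exchanging knockout and wild type in 1 series. It therefore does not show that the sharing exceeds chance.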

How the results depend on the processing

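No test in this part was chosen after the results were seen. No value changed direction past its test under any alternative. Of 230 gene values, 189 kept their side of the threshold under every alternative that could be run. Of 68 list tests 40 were called, and 28 of the 68 stayed on their side of the threshold under every alternative, the estimated correlation included. With the threshold of at least 2-fold, 830 genes were called in the type I knockout, 1352 in the type II knockout, 83 between the wild-type groups and 495 in the same direction in both knockouts, by construction fewer. Without the filter on dim probes 109 genes differed between the wild-type groups. Array weights gave 825 genes whose change differed between the knockouts and 779 between the wild-type groups, and the block for the title number gave 539 whose change differed, and the cause was not tested. With an estimated correlation 4 lists were called in the type I knockout and 2 in the type II knockout.

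Leaving out each array in turn gave 2108 to 3622 genes in the type I knockout, 3188 to 4443 in the type II knockout, 170 to 673 whose change differed, 39 to 251 between the wild-type groups, 1501 to 2134 called in the same direction in both, correlations of 0.688 to 0.726, and 19 to 22 and 16 to 20 lists. The count of changes that differed was 207 and 226 without wild-type replicates 2 and 3 and 188 and 194 without knockout replicates 1 and 2 of the type I series. It was 170 and 190 without wild-type replicates 1 and 3 and 673 without knockout replicate 3 of the type II series. Of the 230 gene values, 34 lost their call when some array was left out and 21 without the filter on dim probes.

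The replicate numbers were also fitted as a block. With the replicate block 3171 genes were called in the type I knockout, 4309 in the type II knockout, 324 whose change differed and 2098 in the same direction in both, with 20 and 17 lists. Arrays of the same replicate number deviated from their group means with correlations of 0.168, 0.059 and 0.359 in the type I series and 0.082, 0.028 and 0.141 in the type II series. Of 6 knockout arrays, 3 correlated best with the wild-type array of their own replicate number and 5 with one of their own title number. In the type I series several arrays of each genotype share a title number, which makes such a match more likely. The labels thus link wild-type and knockout arrays by title number, but do not say what the number marks. The main fit left this link out, and the title number entered only as a block in an alternative. That block raised the count of changes that differed, as given above. The wild-type groups cannot be compared under these blocks, a block for the slide was not run because no slide is named in the sources used here, and the fits with each knockout's own wild type only give no value for the difference or for the wild-type groups. Signal over background limits the genes below background in a group, for which only bounds are given.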

Other observations

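The tests that set the muscle score against the endothelium score were chosen only after the results were seen.

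Of 7 melanocyte markers 0 rose and 4 fell in the type II knockout (0 and 4 adjusted over the list alone), with the melanin synthesis genes Tyrp1 at -4.33 ± 0.91 and Dct at -2.77 ± 0.66 against wild type, but the list was not called (median -0.97, -0.69 with genes below background at their bound, camera adjusted p = 0.108, 0.0206 to 0.454 over 25 alternatives). It was called without the filter on dim probes (0.0341) and without wild-type replicate 3 (0.0206) or knockout replicate 1 (0.0407). The type I knockout had 0 risen and 1 fallen (0 and 1 adjusted over the list alone, median -0.84, -0.31 with bounds, camera adjusted p = 0.305). Of 10 macrophage and monocyte markers 1 rose and 6 fell in the type II knockout (1 and 7 adjusted over the list alone, camera adjusted p = 0.04, adjusted p = 0.454 with an estimated correlation), with the mannose receptor gene Mrc1 at -0.88 ± 0.21 and F13a1 at -0.76 ± 0.17. This call was also lost under 8 other alternatives, among them those without wild-type replicate 1 (0.0824), knockout replicate 1 (0.0938) or knockout replicate 2 (0.0717) of its series or wild-type replicate 3 of the other series (0.0522), in a range of 0.00696 to 0.454. In the type I knockout 0 rose and 1 fell (0 and 1 adjusted over the list alone, median -0.10, mean -0.04, camera adjusted p = 0.805). Of 3 Schwann cell and nerve markers 1 rose and 1 fell in each knockout (1 and 1 adjusted over the list alone, medians 0.03 and -0.09, mean 0.62 in the type II knockout, camera adjusted p = 0.475 and 0.417). Mbp, a myelin gene, rose by 1.25 ± 0.12 in the type I knockout and by 2.58 ± 0.12 in the type II knockout, and the call in the type I knockout was lost with the mean of all its probes (0.248, 2.61e-06 to 0.248 over 24 alternatives).

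Of 4 neutrophil markers 1 rose and 0 fell in the type I knockout (1 and 0 adjusted over the list alone, median 0.74, 0.50 with bounds, camera adjusted p = 0.0499, adjusted p = 0.307 with an estimated correlation), a call also lost without background correction (0.0629), with the mean of all probes (0.0531), with array weights (0.127), without wild-type replicates 1, 2 or 3 or knockout replicate 3 of its series (0.065, 0.056, 0.0839 and 0.123) and without wild-type replicate 2 or knockout replicates 2 or 3 of the other series (0.0519, 0.0523 and 0.0517), in a range of 0.0192 to 0.307. In the type II knockout 3 rose and 0 fell (3 and 0 adjusted over the list alone, median 1.00, 0.70 with bounds, camera adjusted p = 0.0796, 0.023 to 0.411 over 24 alternatives, called with median scaling (0.0273), without knockout replicate 1 (0.023) and without knockout replicate 3 of the other series (0.0399)), with Csf3r, a growth factor receptor of granulocytes, at 1.05 ± 0.30 (adjusted p = 0.0165, 0.00281 to 0.0631 over 23 alternatives, lost without wild-type replicate 1 (0.0631) or knockout replicate 3 (0.0504) and with array weights (0.0522)). No mast cell marker rose or fell in the type I knockout (0 and 0 adjusted over the list alone, median -0.23, placed upward by camera, adjusted p = 0.993), and erythroid markers gave 0 and 2 (0 and 2 adjusted over the list alone, median -0.40, camera adjusted p = 0.317), Langerhans cell markers 0 and 0 (median 0.43, camera adjusted p = 0.36) and T cell markers 0 and 0 (median -0.13, camera adjusted p = 0.891). The same lists in the type II knockout gave 0 and 0 for erythroid markers (median 0.38, camera adjusted p = 0.417), 1 and 1 for Langerhans cell markers (1 and 1 adjusted over the list alone, median -0.19, mean 0.09, camera adjusted p = 0.982) and 0 and 1 for T cell markers (0 and 1 adjusted over the list alone, median -0.29, camera adjusted p = 0.407). H2-Ab1, a class II antigen presentation gene, rose there by 1.63 ± 0.30. Of 8 other intermediate filament genes 1 rose and 3 fell in the type I knockout (1 and 4 adjusted over the list alone, median -0.62, camera adjusted p = 0.189) and 0 rose and 4 fell in the type II knockout (0 and 5 adjusted over the list alone, median -0.80, camera adjusted p = 0.0511, 0.0222 to 0.454 over 25 alternatives), with the lamin gene Lmnb1 at -1.33 ± 0.17. That list was called in the type II knockout with the stricter filter (0.0322), the mean of all probes (0.0445), the block for the title number (0.046) and a covariate for sex (0.0222), and without wild-type replicate 1 (0.0476) or knockout replicates 1 (0.0235) or 3 (0.0357).

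Of 51 cytosolic ribosomal protein genes 1 rose and 1 fell in the type I knockout (0 and 1 adjusted over the list alone, median -0.04, camera adjusted p = 0.759) and 2 and 2 in the type II knockout (2 and 2 adjusted over the list alone, median 0.01, camera adjusted p = 0.488, 0.0466 to 0.954 over 25 alternatives, called with median scaling (0.0466, median 0.03)). Of 20 cardiolipin and mitochondrial phospholipid enzymes 2 rose and 1 fell, and 3 rose and 2 fell (2 and 1, and 2 and 1, adjusted over the list alone, medians -0.01 and -0.14, camera adjusted p = 0.774 and 0.982), with the glycerol phosphate dehydrogenase gene Gpd2 at 1.48 ± 0.26 in the type II knockout. Of 4 hair keratin-associated genes 0 rose and 0 fell, and 0 rose and 1 fell (0 and 0, and 0 and 1, adjusted over the list alone, medians -0.09 and -0.34, camera adjusted p = 0.993 and 0.488). No gene of the sex-linked list, 4 measured, was called in either knockout. This does not show that the sexes were balanced. By these genes all type I knockout arrays read as male, whereas every other group held arrays of both sexes. The spread within a mixed group was large, with Xist at 4.80, 8.57 and 4.62 in the wild type of the type I series.

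The lower markers of fibroblasts, adipocytes and muscle form the third pattern weighed. A lower share of all tissue below the epidermis would lower the markers of muscle and endothelium alike. In the type II knockout the muscle score fell further than the endothelium score, with a difference of -1.29 ± 0.29. Endothelial genes may themselves respond to the knockout, however (1 marker rose and 1 fell), and a rise could hide a loss. The comparison therefore cannot exclude a lower share of all such tissue. In the type I knockout the difference was -0.41 ± 0.29, not clearly beyond its error, so a lower share of all such tissue cannot be told apart from separate changes there. Quantile normalization was not the source, since with median scaling the list medians of these 3 cell types in both knockouts lay between -1.66 and -0.48. A lower share of all tissue below the epidermis, a lower amount of muscle and fat tissue in the pieces taken and a lower expression of these genes all stay open.

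Genes beside the deleted clusters were examined for the hypothesis that the deletion changes its neighbours. Of the 20 nearest tested genes, 5 were called in the type I knockout, against 28.0% of all other genes and 10 of the same genes in the other knockout, and for the type II cluster 9 were called, against 37.7% and 8 (1-sided Fisher's exact test p = 0.698 and 0.323). With 20 genes this leaves the hypothesis undecided. Within the type II cluster, Gm5477, which was picked out after its values were seen, was at least 7.35-fold higher in the type I knockout. In the type II knockout it changed by -0.09 ± 0.16 (adjusted p = 0.682). As it lies within the cluster deleted there, its difference between the knockouts need not be a different response.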
